A study of Homo sapiens with 38 samples.

How the data were processed

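Gene-level RNA sequencing values were taken for 38 libraries of HUES8 human embryonic stem cells at stages 0 to 5 of a directed differentiation towards pancreatic beta cells. Per the labels, clusters of whole cells were frozen in RNAlater, and libraries were sequenced on an Illumina NextSeq 500. The deposited files give for each gene an expected count, made by the authors with RSEM on the human genome GRCh38. The same deposited files give TPM, counts scaled by transcript length and to a fixed total per library, which the authors obtained from RSEM. The version of RSEM, the aligner and the gene annotation are not given in the sources used here. The files hold 57992 genes, of which 57388 were matched by Ensembl identifier to GENCODE release 29 for symbols, positions and gene types. The libraries held between 5533329 (stage 3, S227) and 9489086 (stage 1, S230) expected counts.

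Stages came from the labels (n = 5, 7, 6, 7, 7 and 6) and culture numbers (S227 to S243) from the titles. The series text gives fewer replicates per stage than the files hold. It also gives a number of reads per library above the expected counts here, but reads and counts assigned to genes are unlike measures. The comparisons, tests, gene lists, named genes and most alternatives were set before the data were examined. Neighbouring stages were compared, and stage 5 with stage 0. Expected counts were rounded to whole numbers, genes were kept by filterByExpr with the stage as group (18639 tested, 39353 left out), and libraries were scaled by TMM. A quasi-likelihood model with 1 mean per stage was fitted to all 38 libraries in edgeR 4.0.16 (R 4.3.3), with 5.48 prior degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p below 0.05, two-sided. The SE of a log2 fold change was its size divided by the square root of F. Differences among all 6 stages were tested with 5 coefficients at once.

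Gene lists were tested with camera in limma 3.58.1, a competitive test, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over 180 tests. The lists covered pluripotency, mesendoderm and definitive endoderm, gut tube regulators, pancreatic progenitor, endocrine transcription factors, islet hormones and secretory granule, and beta cell glucose sensing and exocytosis. Others covered acinar, ductal, liver, intestine, enterochromaffin, neural, mesenchyme, and endothelium and blood cells. Process lists were proliferation, hypoxia and glycolysis, oxidative phosphorylation, cholesterol synthesis, unfolded protein response, p53 targets, immediate early and heat shock, and mitochondrially encoded genes. Signalling lists held targets of retinoic acid, Hedgehog, Notch, BMP, Nodal and activin, WNT and thyroid hormone. A measured member is one that passed the filter, and 377 list and key genes were matched to the files, 372 by symbol and 5 by identifier. Counts of list genes below are of measured members. Of the acinar list 7 of 14 members were measured, and of the endothelium and blood list 3 of 10. The enterochromaffin list shares FEV and LMX1A with the endocrine list, and other genes also stand in more than 1 list.

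Genes were named by rule. The rule took key genes fixed for each comparison. It added the 6 highest and the 6 lowest log2 fold changes among called genes with a mean of at least 10 CPM in the higher stage that moved the same way in every culture number with both stages. Clone, LINC and antisense names, pseudogenes, Y-linked genes and XIST were left out of this part. The rule also took up to 3 called members of each list with the largest change. The text names part of these genes. A group with no counts was set to a floor of 3 counts over the group, which gives a lower bound of the fold change. With 1 to 3 counts, the ratio is given with its 95% counting interval. Intervals and floors cover counting error only, since reads were not deduplicated by molecular identifiers. Ratios of mean CPM are plain ratios of stage means and differ slightly from fitted fold changes.

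Relations between stage 4 and stage 5 levels used log2 CPM over the 6 culture numbers with both stages, Pearson's r and Spearman's rho, and all 720 permutations of the pairing, two-sided. Pairing by culture number was checked by correlating each library's deviation from its stage mean between 2 stages. Libraries standing apart were sought within each stage with Dixon's ratio at the 95% critical value. Distances between libraries used correlations of log2 CPM across genes.

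Alternatives were DESeq2 size factors in edgeR, the Wald test of DESeq2 1.42.0, no filter on low counts, a fit of only the 2 stages compared, the culture number as a block, and limma on log2(TPM + 1) and log2(TPM + 0.1). Further ones left out mitochondrially encoded genes before normalization, required a change of at least 2-fold, or left out each culture number or each stage 0 library in turn. Chosen after seeing the data, 4 more left out the stage 2 library of S237, the 2 libraries with the smallest share of mitochondrial counts, the stage 3 library of S243, or all 4 of these. Samples of each pair of stages were also split at random 100 times into groups of the same sizes, the real split included.

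The test was checked on simulated data with 18639 genes, 200 of them changed, with independent libraries and otherwise 1 mean per gene over all stages. At stage 5 against stage 4, edgeR recovered 48% of genes changed 2-fold and 92% of those changed 4-fold, with 7 false calls. Across the 6 comparisons it recovered 38% to 49% at 2-fold and 79% to 93% at 4-fold, with 6 to 11 false calls (4.3% to 8.4% of calls). The share was above 5% at stage 4 against stage 3 (7.1%) and at stage 5 against stage 0 (8.4%). At stage 1 against stage 0, where edgeR made 6 false calls (4.5%), DESeq2 made 24 (14.5%) and limma on log2(CPM + 1) made 10 (7.1%). Within a stage, 103 pairs of libraries had correlations of log2(CPM + 1) of 0.91 to 0.991 over the genes tested. GSTA1 and GSTA2, PRSS1 and PRSS2 are near-identical copies whose reads are hard to assign, and INS overlaps the INS-IGF2 readthrough gene. No sequence reads were used here, so this assignment was not tested. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used for file handling. Splicing, transcript isoforms and the sex-linked genes were not analysed here.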

Results

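RNA was sequenced from HUES8 cells, a human embryonic stem cell line, taken undifferentiated (stage 0) and at 5 successive stages (1 to 5) of a directed differentiation towards pancreatic beta cells, in clusters of whole cells. The 38 libraries comprised 5 at stage 0, 7 at stage 1, 6 at stage 2, 7 at stage 3, 7 at stage 4 and 6 at stage 5. Each library carried 1 of 7 culture numbers (S227, S229, S230, S237, S238, S239 and S243). A culture below means the libraries that share a number. The libraries held between 5533329 and 9489086 expected counts each. Levels are CPM, counts scaled to library size after TMM normalization, as mean ± SD over the libraries of a stage, and log2 fold changes carry their SE. Each named change that passed the test went the same way in every culture number sampled at both stages, unless another number is given. The labels do not state that the libraries of a stage were grown separately, so p-values measure only the spread between these samples.

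Of 18639 genes tested, 15122 (81.1%) differed among the 6 stages, and 10407 of those varied at least 2-fold between stage means. The highest mean lay at stage 0 for 2782 of these genes (26.7%), at stage 1 for 1994, at stage 2 for 1048, at stage 3 for 1243, at stage 4 for 1104 and at stage 5 for 2236 (21.5%). In whole profile, 37 of the 38 libraries correlated best with libraries of their own stage. The stage 2 library of S237 correlated best with the stage 3 library of S237 (r = 0.983 across genes, which are not independent replicates).

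**Figure D1:**
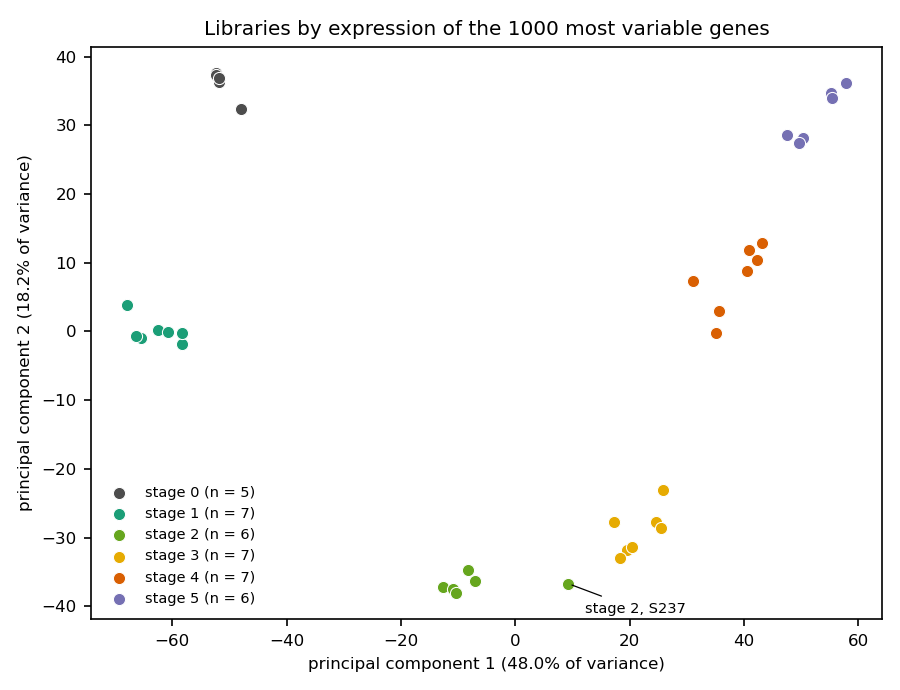
Principal components of the 38 libraries from the 1000 genes with the highest variance of log2 CPM, 1 point per library and 1 colour per stage; the first 3 components hold 48.0%, 18.2% and 14.0% of the variance. The libraries group by stage, except the stage 2 library of S237, which lies near stage 3.

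Stage 1 against stage 0 asked what changed in the first step, which in this protocol leads to definitive endoderm, the embryonic layer that forms gut, liver and pancreas. Endoderm regulators rose from close to the limit of detection, and core pluripotency genes fell. FOXA2 (ENSG00000125798, chromosome 20, 22581005 to 22585455 on GRCh38), a forkhead factor of endoderm, rose from 0.234 ± 0.129 CPM (SD, n = 5) to 186 ± 23.9 CPM (SD, n = 7), a log2 change of 9.53 ± 0.41 (adjusted p = 3.29e-20). EOMES, a T-box factor of mesendoderm, rose 1510-fold to 247 ± 69.9 CPM, and CXCR4, a chemokine receptor used as a surface marker of endoderm, rose 168-fold to 586 ± 127 CPM. POU5F1 (ENSG00000204531, chromosome 6, 31164337 to 31180731), which maintains pluripotency, fell 10.3-fold, from 765 ± 120.1 to 73.9 ± 45.5 CPM (log2 change -3.37 ± 0.26, adjusted p = 1.2e-13).

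All 17 measured members of the mesendoderm and definitive endoderm list rose (adjusted p = 2.17e-36 by the set test, and 2.03e-10 with an estimated correlation). Besides the genes above they included GATA4, a zinc-finger factor of endoderm, up 269-fold to 202 ± 59.7 CPM. They also included FGF17, a growth factor, up 2480-fold to 915 ± 389.5 CPM. The endoderm factor SOX17 (ENSG00000164736, chromosome 8, 54457935 to 54460888) went from 2 counts in all of stage 0, 1 each in S230 and S243, to 109 ± 57.9 CPM, a ratio of 1920 (95% counting interval 530 to 15800). The secreted Nodal and BMP antagonist CER1 rose to 2646 ± 744 CPM. All 8 Nodal and activin targets rose (adjusted p = 3.74e-12, and 0.000396 with an estimated correlation), among them the homeobox gene MIXL1 (147-fold, to 162 ± 45.5 CPM) and the Nodal inhibitor LEFTY1 (8.91-fold, from 112 ± 87.9 to 994.5 ± 353 CPM). Among the gut tube regulators, 7 of 12 rose and 2 fell (adjusted p = 0.000259, and 0.0248 with an estimated correlation). HNF4A, a nuclear receptor of gut epithelium and liver, rose 158-fold.

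Of 18 pluripotency genes, 14 fell, 2 rose and 2 did not pass (adjusted p = 4.67e-11, and 0.00208 with an estimated correlation). The homeobox factor NANOG fell 6.69-fold to 70.1 ± 29.8 CPM, SOX2 fell 32.3-fold to 4.30 ± 3.88 CPM, and the chromatin factor UTF1 fell 69.3-fold. LIN28A, an RNA-binding protein of pluripotent cells, stayed at 1433 ± 329 CPM against 1832 ± 104 CPM at stage 0 and did not pass (adjusted p = 0.17). TDGF1, the Nodal co-receptor, rose 2.04-fold to 972 ± 160 CPM (adjusted p = 0.00927), a call that ended when culture S239 was left out (adjusted p = 0.0576 to 0.0913 over the settings that ended it). The largest falls outside the lists included LECT1, a chondromodulin (317-fold, from 131 ± 55.3 CPM), TXNIP, a thioredoxin-binding protein that restrains glucose uptake (137-fold, from 175 ± 112 CPM), and CAMKV, a kinase-like protein of neurons (94.7-fold). Of 20 proliferation genes, 18 fell (adjusted p = 2.31e-09, and 0.131 with an estimated correlation). TOP2A, the mitotic topoisomerase, fell 3.36-fold to 292 ± 85.1 CPM and MCM4, a subunit of the replicative helicase, 3.07-fold. CDKN1A, the p53-induced inhibitor of the cell cycle, fell 40.6-fold from 15.0 ± 4.95 CPM. It was 1 of 8 p53 targets of 12 that fell while 2 rose (adjusted p = 0.0151, and 0.314 with an estimated correlation). All 3 measured genes of the endothelium and blood list fell (adjusted p = 0.0292, and 0.18 with an estimated correlation), KDR 6.8-fold.

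In the test across all genes, 4676 genes were higher and 4258 lower at stage 1, of which 2691 and 2545 changed at least 2-fold. The counts above were the same when adjusted over the list alone.

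Stage 2 against stage 1 asked how endoderm changed on the way to primitive gut tube. Most endoderm genes fell and most gut tube regulators rose. SOX17 fell 108-fold, from 109 ± 57.9 CPM (SD, n = 7) to 0.994 ± 0.244 CPM (SD, n = 6; log2 change -6.76 ± 0.56, adjusted p = 1.21e-12), and EOMES fell to 0.222 ± 0.214 CPM (log2 change -9.96 ± 0.46). ONECUT1, a homeobox factor of early liver and pancreas, rose 104-fold to 43.4 ± 20.7 CPM (log2 change 6.70 ± 0.56, adjusted p = 1.93e-12). FOXA1, the second forkhead factor of gut endoderm, rose 4.33-fold to 167 ± 65.1 CPM (adjusted p = 2.07e-10).

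Of the 17 mesendoderm and definitive endoderm genes, 13 fell and 2 rose (adjusted p = 3.01e-15, and 3.78e-06 with an estimated correlation). FGF17 fell 874-fold to 1.00 ± 0.666 CPM and CXCR4 fell 5.43-fold to 108 ± 81.3 CPM, whereas GATA4 (202 ± 59.7 to 142 ± 58.2 CPM, adjusted p = 0.145) and FOXA2 (186 ± 23.9 to 243.2 ± 70.5 CPM, adjusted p = 0.158) did not pass. Both calls changed elsewhere, GATA4 without S237 or its stage 2 library (adjusted p = 0.0209 to 0.0421) and FOXA2 on the TPM scales (adjusted p = 0.0113 to 0.0213). All 8 Nodal and activin targets fell (adjusted p = 1.51e-26, and 2.49e-06 with an estimated correlation), the 2 Nodal inhibitors LEFTY1 and LEFTY2 to 0.356 ± 0.445 and 0.680 ± 0.900 CPM from 994.5 ± 353 and 3175 ± 1295 CPM. Without the stage 2 library of S227 their stage 2 means were 0.209 and 0.332 CPM. MYCT1, a MYC target, fell 1020-fold from 183 ± 71.6 CPM. Of 18 pluripotency genes, 12 fell and none rose (adjusted p = 5.74e-07, and 0.034 with an estimated correlation).

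Of 12 gut tube regulators, 8 rose and none fell (adjusted p = 4.78e-05, and 0.00905 with an estimated correlation). HNF4A rose 1.96-fold to 86.7 ± 10.6 CPM and PROX1, a homeobox factor of liver and pancreas, 10.1-fold. TTR, the carrier of thyroxine and retinol made by liver and gut endoderm, rose to 562 ± 273 CPM (log2 change 12.17 ± 0.76), and the peptide NPY rose 1480-fold to 677 ± 337 CPM. Of 10 liver genes, 9 rose (adjusted p = 0.00183, and 0.29 with an estimated correlation). One of them, the fetal serum protein AFP, reached 12.8 ± 18.3 CPM, and its ratio of mean CPM went from 146 to 65.6 without the stage 2 library of S237, and its stage 1 mean from 0.0877 to 0.0528 CPM without the stage 1 library of S229. Of 7 intestine genes, 3 rose and 1 fell (adjusted p = 0.018, 0.123 with an estimated correlation and 0.233 on log2(TPM + 1)). Of the 3 measured genes of the endothelium and blood list, 1 fell (adjusted p = 0.0358, 0.179 with an estimated correlation, and 0.0508 to 0.0577 without S229, S237 or S243 or with the culture number as block). KRT19, an epithelial keratin, rose 1.77-fold in 5 of 6 culture numbers, and this call ended without S238 or S239 (adjusted p = 0.0564 to 0.0696). Of 11 pancreatic progenitor genes, 6 rose and 1 fell (adjusted p = 0.00365, 0.0504 with an estimated correlation and 0.0727 on log2(TPM + 1)). MEIS2, a homeobox cofactor, rose 32.1-fold to 221 ± 44.3 CPM. The pancreatic factor PDX1 (ENSG00000139515, chromosome 13, 27920020 to 27926231) went from 1 count in all of stage 1 to 38.9 CPM in S237 and 4.82 ± 7.32 CPM in the other 5 stage 2 libraries.

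Of 10 BMP targets, 6 rose (adjusted p = 0.00653, and 0.448 with an estimated correlation), including the signal transducer SMAD9 (7.21-fold) and the inhibitor of differentiation ID4 (5.73-fold). The Notch effector HES1 rose 6.64-fold. Of 20 proliferation genes, 8 rose, among them MCM2 2.07-fold, and 1 fell. The list did not pass (adjusted p = 0.0703), but it did so without S230 or without S237 among 7 other settings (adjusted p = 0.00472 to 0.0489).

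In all, 3500 genes were higher and 3557 lower at stage 2. The share of called genes that were higher was 49.6% here and 60.5% on log2(TPM + 1), with 3645 higher and 2377 lower. Adjusted over the list alone, 2 pluripotency genes rose, 1 BMP target fell, 10 liver, 4 intestine and 9 proliferation genes rose, 3 endothelium and blood genes fell, and the other counts were the same.

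Stage 3 against stage 2 asked what changed when gut tube cells were directed to early pancreatic progenitors. At stage 3, 10 of 14 retinoic acid targets and 4 of 11 pancreatic progenitor genes rose, and 8 of 10 BMP targets fell. SOX9, a factor of pancreatic progenitors and duct, rose 3.24-fold, from 16.0 ± 4.22 CPM (SD, n = 6) to 52.0 ± 24.01 CPM (SD, n = 7; log2 change 1.70 ± 0.26, adjusted p = 4.68e-06). PDX1 rose from 10.5 ± 15.4 to 44.5 ± 18.4 CPM in 5 of 6 culture numbers (adjusted p = 0.00121), a ratio of mean CPM of 4.24 that became 9.23 without the stage 2 library of S237. It was not called when only the 2 stages were fitted (adjusted p = 0.0564). The inhibitor of differentiation ID1, a direct BMP target, fell 8.49-fold to 32.3 ± 21.6 CPM (adjusted p = 0.000266).

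Of 14 retinoic acid targets, 10 rose and none fell (adjusted p = 7.12e-08, and 0.0432 with an estimated correlation). HOXA3, a homeobox gene of the foregut, rose to 45.6 ± 6.84 CPM, with a ratio of mean CPM of 17.4 that became 134 without the stage 2 library of S237. The retinoid-degrading enzyme CYP26A1 rose to 287 ± 51.3 CPM, with a ratio of 8.04 that became 434 without that library. CYP26A1 was not called when only the 2 stages were fitted (adjusted p = 0.107). This was not its first rise. CYP26A1 had been higher at stage 1, at 528.8 ± 125.5 CPM (SD, n = 7), and was at 35.7 ± 85.8 CPM (SD, n = 6) at stage 2. The receptor RARB rose 1.8-fold in 5 of 6 culture numbers (adjusted p = 0.0191, and 0.0583 to 0.135 under the settings that ended the call). Of 10 BMP targets, 8 fell and 1 rose (adjusted p = 4.65e-07, and 0.123 with an estimated correlation), among them the inhibitory SMAD6 (7.07-fold) and SMAD9 (5.84-fold). The Hedgehog receptor PTCH1 fell 1.56-fold, a call that ended without S229 (adjusted p = 0.0644). Of 9 WNT targets, 6 fell and 1 rose (adjusted p = 0.0313, 0.513 with an estimated correlation, and 0.0513 to 0.126 without S227, without S243 or without the stage 2 library of S237).

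Of 11 pancreatic progenitor genes, 4 rose and none fell (adjusted p = 0.0246, and 0.131 with an estimated correlation). MNX1, a homeobox factor of pancreatic buds, rose to 29.2 ± 28.2 CPM, with a ratio of mean CPM of 14.0 that became 9.09 without the stage 3 library of S243. Without that library its stage 3 level was 18.9 ± 7.82 CPM (SD, n = 6), and at stage 1 it had been 24.9 ± 9.88 CPM (SD, n = 7). HNF4A and ONECUT1 did not pass (adjusted p = 0.121 and 0.933). Of 15 endocrine transcription factors, 7 rose and 1 fell (adjusted p = 0.000737, and 0.289 with an estimated correlation). NEUROG3 (ENSG00000122859, chromosome 10, 69571698 to 69573238), which commits progenitors to the endocrine lineage, had no counts at stage 2 and 18.1 ± 25.1 CPM at stage 3, at least 250-fold higher against a floor of 3 counts over the group. Its target NEUROD1 was at least 129-fold higher, at 9.11 ± 11.2 CPM. Without the stage 3 library of S243 the stage 3 levels of NEUROG3 and NEUROD1 were 9.03 ± 8.21 and 5.398 ± 5.98 CPM. Of 17 islet hormone and granule genes, 7 rose and 1 fell (adjusted p = 0.00696, and 0.478 with an estimated correlation). Chromogranin A (CHGA), a granule protein, rose in 5 of 6 culture numbers to 14.3 ± 27.0 CPM. Without the stage 3 library of S243 its stage 3 level was 4.27 ± 5.20 CPM, and its ratio of mean CPM went from 16.5 to 4.93. Its call ended in a fit without S243 (adjusted p = 0.0765). Of 7 acinar genes, 2 rose (adjusted p = 0.0292, 0.286 with an estimated correlation, and 0.0549 to 0.108 with DESeq2, without S227 or without S243), including the digestive proenzyme CPB1, at 74.2 ± 48.8 CPM, whose stage 2 counts all came from S237 (1.52 CPM). Of 10 liver genes, 3 rose (adjusted p = 0.0163, 0.361 with an estimated correlation, and 0.0601 to 0.0732 with DESeq2 or without S227). Large falls included NPY (38-fold), the clotting protein VWF (52.9-fold, from 28.4 ± 23.1 CPM) and KRT19 (3.01-fold). Of 20 proliferation genes, 6 fell (adjusted p = 0.00272, and 0.528 with an estimated correlation).

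In all, 2068 genes were higher and 2325 lower at stage 3. The share of called genes that were higher was 47.1% here and 63.5% on log2(TPM + 1), with 2110 higher and 1214 lower. Adjusted over the list alone, 12 retinoic acid targets and 5 liver genes rose, 8 proliferation genes fell and the other counts above were the same.

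Stage 4 against stage 3 asked which genes changed between early and late pancreatic progenitors. Most pancreatic progenitor genes and most hormone and granule genes rose. NKX6-1 (ENSG00000163623, chromosome 4, 84491987 to 84498450), a homeobox factor needed for beta cells, rose from 0.0942 ± 0.139 to 109 ± 33.4 CPM (SD, n = 7 at each stage; log2 change 9.91 ± 0.43, adjusted p = 1.21e-17), and its ratio of mean CPM went from 1160 to 2250 without the stage 3 library of S239. SOX9 rose 6.31-fold to 328 ± 40.5 CPM (log2 change 2.66 ± 0.24, adjusted p = 8.92e-11) and PDX1 rose 2.95-fold to 131 ± 21.9 CPM (log2 change 1.56 ± 0.43, adjusted p = 0.00589).

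Of 11 pancreatic progenitor genes, 8 rose and 2 fell (adjusted p = 5.59e-11, and 3.02e-05 with an estimated correlation). PTF1A, a factor of multipotent and acinar progenitors, rose 323-fold to 30.4 ± 13.1 CPM and GP2, a surface marker of pancreatic progenitors, 57.2-fold to 9.76 ± 3.80 CPM. Of 8 ductal genes, 3 rose and 1 fell (adjusted p = 0.00237, and 0.0432 with an estimated correlation), with the bicarbonate transporter SLC4A4 up 18.7-fold to 803 ± 131 CPM. Of 17 islet hormone and granule genes, 12 rose (adjusted p = 3.33e-08, and 0.123 with an estimated correlation). Insulin (INS, ENSG00000254647, chromosome 11, 2159779 to 2161341) went from 1 count in all of stage 3 to 19.97 ± 16.2 CPM, a ratio of 1050 (95% counting interval 189 to 41700). Glucagon (GCG) reached 169 ± 108 CPM and somatostatin (SST) 185 ± 139 CPM, from 0.461 ± 0.591 and 0.527 ± 0.888 CPM. The stage 3 mean was 0.281 CPM for GCG without S238 and 0.197 CPM for SST without S230. CHGA rose 22.2-fold to 316 ± 158 CPM, and its ratio of mean CPM became 74.1 without the stage 3 library of S243. Of 18 beta cell genes of glucose sensing and exocytosis, 12 rose and 1 fell (adjusted p = 7.91e-11, and 0.021 with an estimated correlation), among them the potassium channel subunit ABCC8 (81.5-fold) and the granule zinc transporter SLC30A8 (25.2-fold). Of 15 endocrine transcription factors, 8 rose and 1 fell (adjusted p = 0.0021, and 0.326 with an estimated correlation). PAX6, a factor of all endocrine cells, rose 9.55-fold, whereas NEUROG3 fell 6.6-fold to 2.69 ± 1.85 CPM, a call that ended without the stage 3 library of S243 (adjusted p = 0.0635 to 0.0706, ratio of mean CPM 3.35 in place of 6.71). NEUROD1 rose 3.59-fold to 32.6 ± 22.3 CPM (adjusted p = 0.0152, and 0.0505 to 0.0657 without S229, without S238 or with only the 2 stages fitted), and its ratio became 6.05 without the stage 3 library of S243. NKX2-2, INSM1 and the proliferation marker MKI67 did not pass (adjusted p = 0.827, 0.712 and 0.989).

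Of 14 retinoic acid targets, 6 fell and 1 rose (adjusted p = 0.00225, and 0.344 with an estimated correlation). CYP26A1 fell 489-fold to 0.561 ± 0.239 CPM (adjusted p = 1.77e-07). Of 10 liver genes, 5 fell and 1 rose (adjusted p = 0.00237, and 0.264 with an estimated correlation), with the apolipoprotein APOA2 down 69.8-fold from 62.8 ± 22.5 CPM. Of 10 BMP targets, 7 rose and 2 fell (adjusted p = 0.00237, and 0.366 with an estimated correlation), including ID2 (7.7-fold) and ID3 (9.46-fold, to 326 ± 243.1 CPM). Of 11 neural genes, 5 rose (adjusted p = 0.00109, and 0.186 with an estimated correlation). Of 13 mesenchyme genes, 5 rose and 1 fell (adjusted p = 0.291 by the set test), the growth factor receptor PDGFRA 10.2-fold. In the stage 4 library of S230 the mesenchyme genes HAND1 and COL3A1 were at 42.2 and 745 CPM. In the other stage 4 libraries they were at 0.191 ± 0.286 and 13.6 ± 22.0 CPM (SD, n = 6). These 2 genes were singled out after their values were seen. Of 20 proliferation genes, 6 fell (adjusted p = 0.0142, and 0.639 with an estimated correlation), MCM2 1.58-fold.

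In all, 2386 genes were higher and 1942 lower at stage 4. Adjusted over the list alone, 3 pancreatic progenitor genes, 2 endocrine factors, 8 retinoic acid targets, 8 liver genes and 1 neural gene fell, 2 liver genes, 15 beta cell genes, 8 BMP targets and 8 mesenchyme genes rose, and the other counts above were the same.

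Stage 5 against stage 4 asked what changed as pancreatic progenitors entered the endocrine stage, the last one sampled. Most hormone and granule genes and most endocrine factors rose, and the progenitor factors SOX9 and PTF1A fell. GCG (ENSG00000115263, chromosome 2, 162142873 to 162152404) rose 13-fold, from 169 ± 108 CPM (SD, n = 7) to 2186 ± 1029 CPM (SD, n = 6; log2 change 3.70 ± 0.47, adjusted p = 1.27e-07). INS rose 8.09-fold to 162 ± 182 CPM (log2 change 3.02 ± 0.51, adjusted p = 4.46e-05), a ratio of mean CPM of 8.10 that became 4.47 without the stage 5 library of S227. SOX9 fell 5.05-fold to 64.9 ± 11.6 CPM (log2 change -2.34 ± 0.26, adjusted p = 5.87e-09).

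Of 15 endocrine transcription factors, 13 rose and none fell (adjusted p = 7.2e-10, and 0.0393 with an estimated correlation). NEUROD1 rose 4.95-fold to 162 ± 60.3 CPM, NKX2-2 6.36-fold to 102 ± 33.8 CPM, and PAX4, which favours the beta and delta lineages, 7.85-fold to 76.1 ± 22.5 CPM. ISL1, a factor of maturing islet cells, rose 2.82-fold from 55.7 ± 20.5 CPM, and had been at 71.1 ± 55.3 CPM at stage 2 (SD, n = 6). MAFA, a factor of mature beta cells, reached 1.30 ± 1.06 CPM (5.73-fold), below its 3.295 ± 0.954 CPM at stage 0 (SD, n = 5). NEUROG3 rose 23.3-fold to 63.8 ± 66.5 CPM, a ratio of mean CPM of 23.7 that became 13.6 without the stage 5 library of S227. Of 17 islet hormone and granule genes, 14 rose (adjusted p = 4.67e-09, and 0.0845 with an estimated correlation). CHGA rose 5.95-fold to 1882 ± 1880 CPM (ratio of mean CPM 3.57 without the stage 5 library of S227), and SST did not pass (185 ± 139 to 418.5 ± 447 CPM, adjusted p = 0.0627), with a stage 5 level of 238.3 ± 82.5 CPM without the library of S227. It passed under 2 settings, without S230 among them (adjusted p = 0.0397 to 0.0445). Of 18 beta cell genes, 12 rose (adjusted p = 2.72e-13, and 0.00909 with an estimated correlation), SLC30A8 32.3-fold to 201 ± 104 CPM and ABCC8 10.2-fold to 93.8 ± 42.9 CPM.

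Of 11 pancreatic progenitor genes, 2 rose and 3 fell (adjusted p = 0.127, and towards lower 0.0499 with the culture number as block and 0.0443 on log2(TPM + 1)). PTF1A fell 5.16-fold to 5.87 ± 3.83 CPM, and RFX6, a factor of gut and islet endocrine cells, rose 5.5-fold to 151 ± 20.8 CPM. RFX6 had already been at 111 ± 37.2 CPM at stage 3, and was at 27.4 ± 9.48 CPM at stage 4 (SD, n = 7 each). NKX6-1 was lower in 5 of 6 culture numbers, at 84.9 ± 41.5 against 109 ± 33.4 CPM, and did not pass (adjusted p = 0.358, and 0.0237, lower, with the culture number as block). PDX1 was lower in each of the 6 culture numbers and did not pass (131 ± 21.9 to 73.8 ± 15.3 CPM, adjusted p = 0.202, and 0.000762 with only the 2 stages fitted). Of 8 Notch targets, 5 fell and 1 rose (adjusted p = 0.00327, and 0.182 with an estimated correlation), with HEY1 down 18.8-fold from 70.8 ± 15.6 CPM (ratio of mean CPM 19.0, and 30.4 without the stage 5 library of S230). HES1, the Notch effector that holds back NEUROG3, fell 2.04-fold to 66.9 ± 22.9 CPM (adjusted p = 0.0241), a call that ended without S227, S238 or S239 (adjusted p = 0.064 to 0.0968). Of 20 proliferation genes, 11 fell (adjusted p = 9.83e-06, and 0.289 with an estimated correlation), MKI67 1.84-fold in 5 of 6 culture numbers. Of 10 BMP targets, 5 fell and 1 rose (adjusted p = 3.01e-05, and 0.193 with an estimated correlation), ID3 8.11-fold and SMAD7 6.14-fold. Of 4 Hedgehog targets, 2 rose (adjusted p = 0.0137, 0.0724 with an estimated correlation and 0.129 on log2(TPM + 1)), PTCH1 2.18-fold to 126 ± 9.49 CPM.

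Of the lists of other cell types, those of enterochromaffin, intestine, liver and neural genes were called higher, and the acinar, ductal, mesenchyme, and endothelium and blood lists did not pass (adjusted p = 0.772, 0.964, 0.939 and 0.271). All 8 enterochromaffin genes, markers of serotonin-making endocrine cells of the gut, rose (adjusted p = 1.94e-14, and 3.25e-05 with an estimated correlation). TPH1 (ENSG00000129167, chromosome 11, 18017564 to 18042426), which catalyses the first step of serotonin synthesis, rose 45.6-fold from 4.96 ± 1.30 to 228 ± 86.6 CPM (log2 change 5.51 ± 0.30, adjusted p = 1.07e-16), and the tachykinin TAC1 rose 24-fold. Of 7 intestine genes, 4 rose (adjusted p = 0.00339, and 0.0432 with an estimated correlation). CDX1, a homeobox factor of intestine, was at least 80.3-fold higher against a floor of 3 counts over the group, at 4.51 ± 2.05 CPM. Of 10 liver genes, 7 rose and 1 fell (adjusted p = 0.00044, and 0.187 with an estimated correlation), with the fibrinogen chain FGB up to 1027 ± 484 CPM (ratio of mean CPM 115, and 256 without the stage 4 library of S230). Of 11 neural genes, 3 rose, and 6 adjusted over the list alone (adjusted p = 0.00676, and 0.264 with an estimated correlation). The largest rises in the whole comparison included AGR2, a disulfide isomerase of mucus-secreting epithelium (607-fold, to 636 ± 212 CPM), AOC1, the histamine-degrading diamine oxidase (297-fold), and CLCA1, a goblet cell product (at least 209-fold, to 11.5 ± 9.08 CPM). Of 13 mitochondrially encoded genes, 3 rose (adjusted p = 0.0103, 0.677 with an estimated correlation, and 0.0508 without S227), and of 20 oxidative phosphorylation genes 4 rose (adjusted p = 0.126, and 0.0456 with the culture number as block).

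In all, 2195 genes were higher and 1789 lower at stage 5. Adjusted over the list alone, 14 endocrine factors, 15 hormone and granule genes, 14 beta cell genes, 3 Hedgehog targets and 7 mitochondrially encoded genes rose, 14 proliferation genes and 7 BMP targets fell, and the other counts above were the same.

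**Figure D2:**
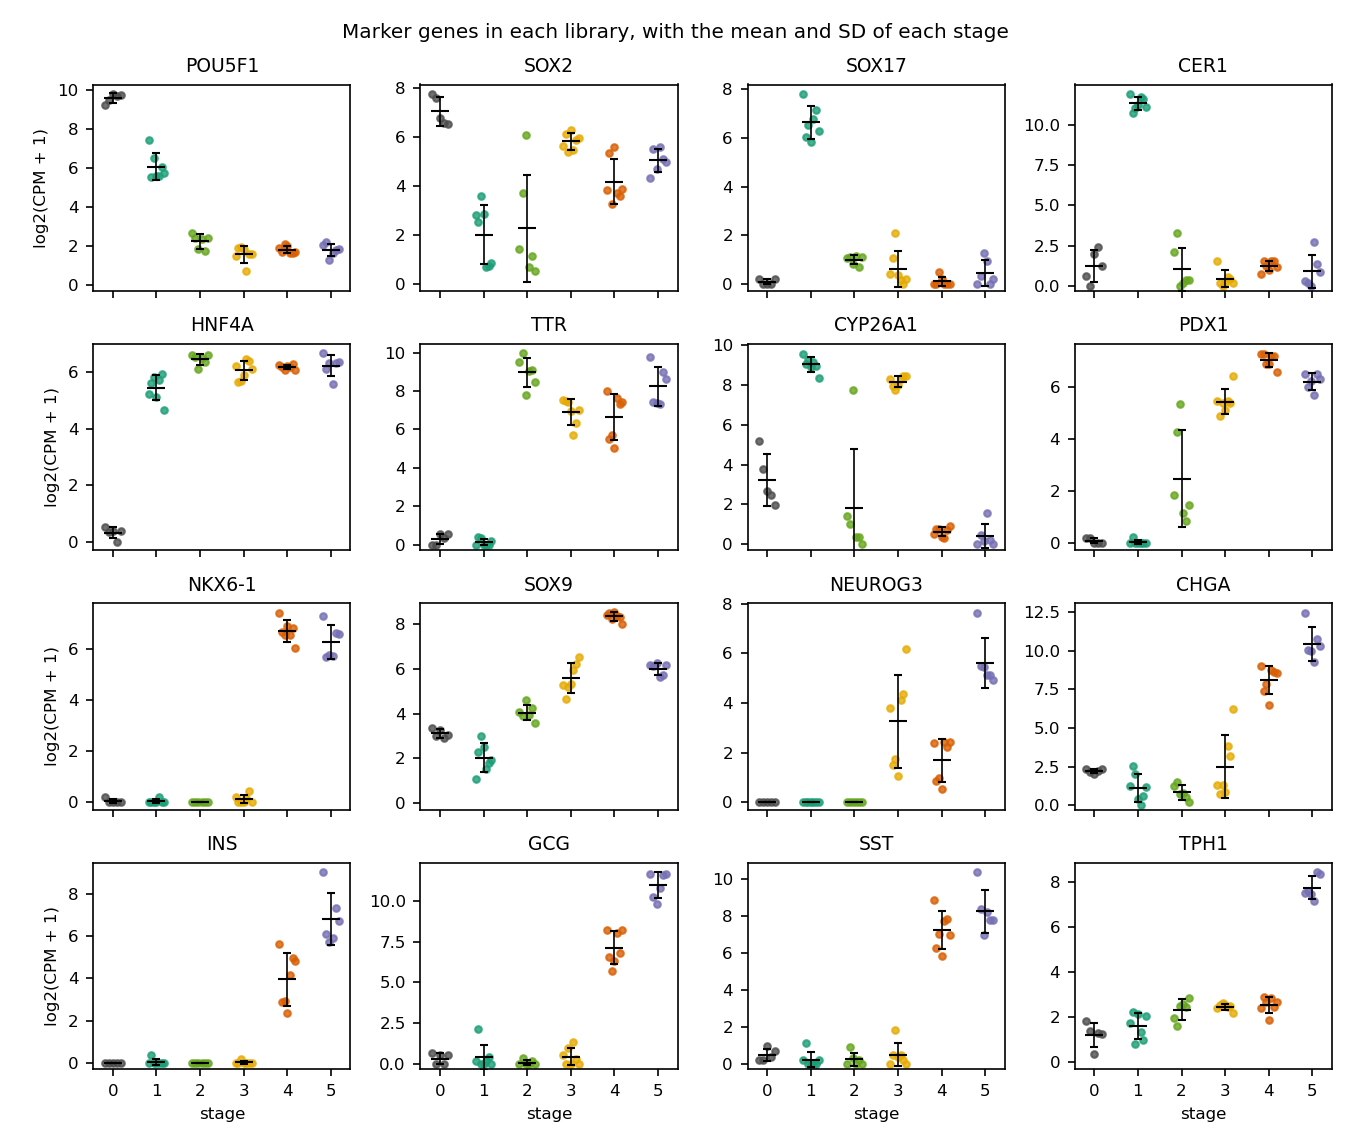
Levels of 16 named genes in each of the 38 libraries by stage, as log2(CPM + 1), with 1 point per library and bars for mean ± SD. POU5F1 is highest at stage 0, SOX17 at stage 1, NKX6-1 at stage 4 and GCG and INS at stage 5.

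**Figure D3:**
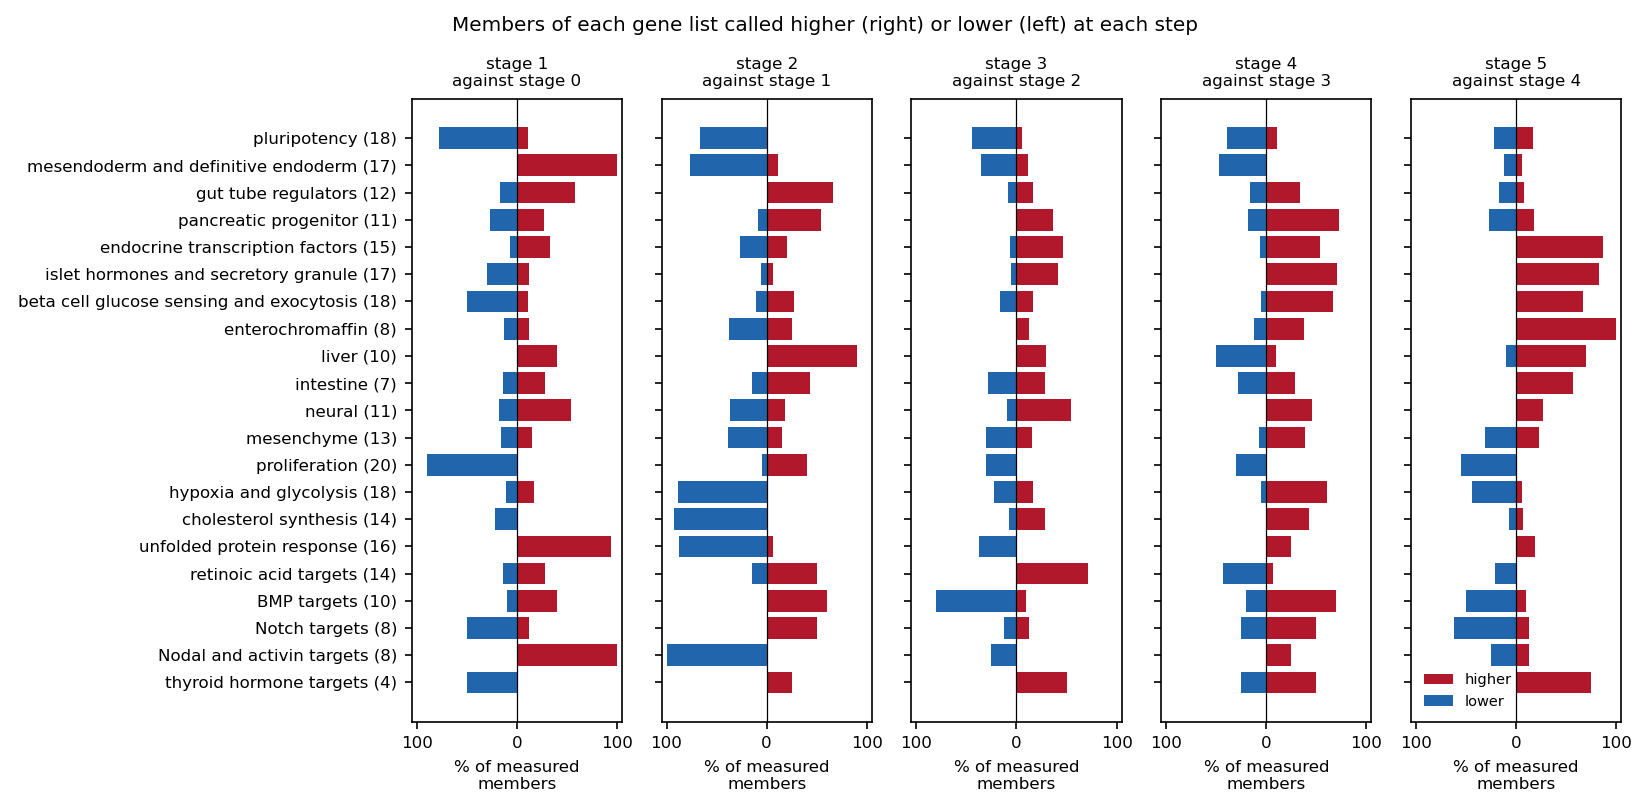
Percent of the measured members of 21 gene lists called higher (right, red) or lower (left, blue) at each of the 5 steps between neighbouring stages. All 17 mesendoderm and definitive endoderm genes were higher at stage 1 against stage 0, and all 8 enterochromaffin genes at stage 5 against stage 4.

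Stage 5 against stage 0 measured the whole course. POU5F1 fell 297-fold to 2.55 ± 0.757 CPM (SD, n = 6; log2 change -8.21 ± 0.35) from 765 ± 120.1 CPM (SD, n = 5), and LIN28A fell 27.1-fold to 67.5 ± 28.9 CPM. INS and NEUROD1 had no counts at stage 0, and their stage 5 levels were at least 1850-fold and 1840-fold above a floor of 3 counts over the group. Without the stage 5 library of S227, the stage 5 level of INS was 89.3 ± 45.7 CPM in place of 162 ± 182 CPM. GCG rose to 2186 ± 1029 CPM (log2 change 12.78 ± 0.88, adjusted p = 5.71e-15). PDX1 went from 2 counts in all of stage 0, 1 each in S230 and S237, to 73.8 ± 15.3 CPM, a ratio of 1260 (95% counting interval 348 to 10400).

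All 18 pluripotency genes were lower at stage 5 (adjusted p = 5.85e-27, and 1.5e-05 with an estimated correlation). DPPA4 fell 892-fold from 1040 ± 177 CPM, and the zinc-finger factor ZSCAN10, at 69.5 ± 1.28 CPM at stage 0, was at least 1000-fold lower. All 20 proliferation genes were lower (adjusted p = 1.32e-16, and 0.034 with an estimated correlation), MKI67 3.77-fold and the mitotic checkpoint kinase BUB1 8.22-fold. All 11 pancreatic progenitor genes were higher (adjusted p = 6.76e-08, and 0.000475 with an estimated correlation), as were 10 of 12 gut tube regulators (adjusted p = 6.64e-10, and 0.000172 with an estimated correlation). All 17 hormone and granule genes were higher (adjusted p = 1.76e-06, and 0.18 with an estimated correlation), as were 17 of 18 beta cell genes (adjusted p = 5.62e-08, and 0.0578 with an estimated correlation) and 14 of 15 endocrine factors, with 1 lower (adjusted p = 8.3e-08, and 0.091 with an estimated correlation). The lower factor was MAFA (log2 change -1.33 ± 0.52), named here after its value was seen. Of the lists of other cell types, 7 of 8 enterochromaffin genes (adjusted p = 1.33e-05, and 0.0181 with an estimated correlation) and 6 of 7 intestine genes were higher (adjusted p = 0.000494, and 0.019 with an estimated correlation). All 10 liver genes were higher (adjusted p = 3.42e-05, and 0.123 with an estimated correlation), as were 9 of 11 neural genes, with 1 lower (adjusted p = 0.00272, and 0.207 with an estimated correlation). Of 8 ductal genes, 7 were higher and 1 lower (adjusted p = 0.0238, 0.127 with an estimated correlation, and 0.065 to 0.085 on log2(TPM + 1) or with the culture number as block). All 3 measured genes of the endothelium and blood list were lower (adjusted p = 0.00365, and 0.0432 with an estimated correlation). The filter left out the other 7 of its 10 members. The mesenchyme list, with 5 higher and 4 lower of 13, and the acinar list, with 5 higher of 7, did not pass (adjusted p = 0.604 and 0.134), the latter passing without S237 or its stage 2 library (adjusted p = 0.0304 to 0.0485). Of 20 oxidative phosphorylation genes, 12 were lower (adjusted p = 0.00816, and 0.637 with an estimated correlation). These counts were the same when adjusted over the list alone.

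In all, 5925 genes were higher and 4948 lower at stage 5 than at stage 0, of which 4216 and 2862 changed at least 2-fold. The share of called genes that were higher was 54.5% here and 73.1% on log2(TPM + 1), with 7848 higher and 2890 lower, and the median log2 change of all genes lay 0.294 higher on the TPM scale than in CPM (0.113 higher at stage 2 against stage 1).

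Whether cultures with more NKX6-1 at stage 4 had more INS at stage 5 was asked over the 6 culture numbers with both stages, as 1 of 4 relations. Pearson's r was 0.744 (exact two-sided permutation p = 0.106, adjusted 0.172) and Spearman's rho 0.486 (exact p = 0.356, adjusted 0.474), so the relation did not pass. Without S227 and S230, the 2 cultures farthest from the median NKX6-1, r was -0.685. On log2(TPM + 1), r was 0.544, and 0.129 without its 2 farthest cultures (S227 and S237), so the relation rested on the farthest cultures. The sign of the remainder changed with the scale and with the cultures left out, which cannot be told apart. NEUROG3 at stage 4 and INS at stage 5 had r = 0.804 (exact p = 0.031, adjusted 0.122) and rho = 0.771 (exact p = 0.103, adjusted 0.411), and r = 0.813 without the 2 farthest cultures (S237 and S238). These cultures formed 2 groups, and the 2 left out were 1 of each. S229, S230 and S237 had 0.4376 to 0.955 CPM of NEUROG3 and 52.76 to 67.45 CPM of INS. S227, S238 and S239 had 3.685 to 4.359 and 105.7 to 524.3 CPM. In whole profile at stages 3, 4 and 5, each of these libraries correlated best with another of its own group. At stage 0, without S227 and S229, S230 paired with S237 and S238 with S239. The grouping did not hold for S230 at stage 1 (best with S239) or for S229 at stage 2 (best with S227). At stage 3, NEUROG3 was already at 1.101 to 2.385 CPM in S229, S230 and S237 and at 12.94 to 19.43 CPM in S227, S238 and S239. The grouping was thus present before stage 4, and its cause was not tested. PDX1 and INS had r = 0.631 (exact p = 0.167) and rho = 0.543 (exact p = 0.297), with r = 0.180 without the 2 farthest (0.633 on log2(TPM + 1)). NKX6-1 and CHGA had r = 0.677 (exact p = 0.172) and rho = 0.257 (exact p = 0.658), with r = -0.835 without the 2 farthest (0.136 on log2(TPM + 1)). No sequencing batch was given in the labels.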

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

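The relations of stage 4 NKX6-1 and NEUROG3 with stage 5 INS were planned, and the other tests of explanations in this part were chosen after the results were seen. Within stages, 15 of 148 sets of values had a library standing apart by Dixon's ratio at 95%, where about 7.4 would be by chance at 1 in 20. The stage 2 library of S237 accounted for 4 of them and the stage 3 library of S243 for 3.

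The stage 2 library of S237 had stage 3 features. RFX6 was at 118 CPM there (7.20 to 12.9 in the other stage 2 libraries), CYP26A1 at 211 CPM (0 to 1.69), HOXA3 at 14.0 CPM (0.286 to 0.461), and KRT19 was low at 355 CPM (883 to 1279). On a scale from stage 2 (0) to stage 3 (1) its position was 0.79 on 291 genes higher at stage 3 and 0.73 on 160 lower ones, whereas the stage 3 library of S237 stood at 0.94 or above on both, which argues against a swap of these 2 libraries. The value of 0.79 also lay below the stage 3 range of 0.88 to 1.11. The stage 3 libraries that set this range helped choose the genes, and the stage 2 library of S237 did not. A stage 3 sample under a stage 2 label therefore stays open. The stage 3 share estimated from rising and from falling genes differed by at least 0.2 over 35 pairs of libraries. On linear CPM the stage 3 library of S230 itself stood at 0.68 on rising and 0.96 on falling genes. Such a difference therefore cannot decide on RNA of both stages in 1 library, which stays open. Other candidate explanations that stay open are a faster or later-sampled culture, and neither was tested.

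Endocrine genes differed between cultures at stage 5. NEUROG3 was at 199 CPM in S227 (29.3 to 43.6 in the others), and INS at 524 CPM (89.3 ± 45.7 in the others, SD, n = 5). Over the 6 cultures the rho of stage 5 INS was 0.486 with stage 4 NKX6-1 and 0.771 with stage 4 NEUROG3, neither past the threshold, so whether earlier levels set the INS level stays open at this number of cultures. In S227, 42 of 50 genes of the 3 endocrine lists (84.0%) were highest, but this was counted after INS, NEUROG3 and CHGA were seen to be high there and such genes move together, so it leaves open whether these clusters held a larger endocrine share. All 13 mitochondrially encoded genes, which can reflect RNA quality, were also highest in S227, as were 17 of 20 oxidative phosphorylation and 12 of 16 unfolded protein response genes, and 14 of 20 proliferation genes were lowest, so a difference in RNA quality stays open too.

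Enterochromaffin genes rose at stage 5 in all 8 members, in clusters directed to beta cells. FEV and LMX1A also stand in the endocrine list, and the other 6 members rose as well (p = 1.1e-12 by the set test, and 2.84e-06 with an estimated correlation), which argues against these 2 genes carrying the rise. The smallest log2 change of the 6 was 2.09. Whether a separate cell type or the endocrine cells themselves made these transcripts cannot be read from whole clusters and was not tested.

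The stage 3 library of S243 was highest in PDX1 (84.3 CPM, others 28.2 to 42.8) and lowest in RFX6 (36.0 CPM, others 87.7 to 141) and RARB (48.6 CPM, others 85.6 to 120.5). The stage 2 library of S229 had the fewest genes with a count (21181, others 24172 to 25617). Mitochondrially encoded genes took 4.25% of counts in the stage 5 library of S227 (others 2.15% to 2.83%) and 1.11% in the stage 4 library of S243 (others 1.84% to 2.34%). At stage 0, NANOG was lowest in S230 (359 CPM, others 468 to 516) and TDGF1 highest in S237 (640.2 CPM, others 409 to 449). Single counts set apart S230 in INS at stage 3 (0.119 CPM, others 0) and in NKX6-1 at stage 0 (0.144 CPM, others 0).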

How the results depend on the processing

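Of 563 results for named genes, 549 were called, 452 of these kept their direction and side of the threshold under every alternative run for single genes (the 2-fold rule was applied to counts alone), 97 lost the call under at least 1, and 1 reversed. Calls were lost most often on log2(TPM + 1) (52) and log2(TPM + 0.1) (46), without S239 (40) and without S238 (35), and never with DESeq2 size factors or without mitochondrial genes. DIO1 at stage 2 against stage 1 rose in the main test, and its log2 change was -0.18 without replicate S237 (up to 3.62 without another culture), -0.70 with the stage 2 library of S237 left out and -1.15 with all 4 libraries left out, the last 2 chosen after seeing the data. On log2(TPM + 1), lower genes numbered 1214 at stage 3 against stage 2, 1291 at stage 4 against stage 3 and 2890 at stage 5 against stage 0, and on log2(TPM + 0.1) 1208, 1199 and 2813; the cause was not tested. Requiring a change of at least 2-fold, by construction a stricter call, left 2691 higher and 2545 lower genes at stage 1 against stage 0, 1930 and 2072 at stage 2 against stage 1, 1217 and 881 at stage 3 against stage 2, 1509 and 880 at stage 4 against stage 3, 1406 and 674 at stage 5 against stage 4, and 2862 lower genes at stage 5 against stage 0. Of 180 list results 82 were called, and 26 with an estimated correlation; of the 82, 67 held under the other alternatives run for lists, which did not include the fits with no filter, with only the 2 stages compared, on log2(TPM + 0.1) or without mitochondrial genes. Leaving out a culture moved the higher genes at stage 3 against stage 2 to between 1421 (without S239) and 2331, and the lower ones to between 1578 (without S229) and 2460. With the culture number as block, 3 gene calls and 3 list calls were lost and 2 and 5 gained; the numbers paired the samples at stage 5 against stage 4 (r = 0.17 to 0.7 for the same number, mean -0.06 for others) and did so less clearly at stage 4 against stage 3 (-0.18 to 0.63, with 6 of 7 numbers over 0.1 and 4 libraries best with their own number). For stage 4 NKX6-1 and stage 5 INS on the TPM scale, r was 0.544 and rho 0.429. Without the 2 farthest cultures the main rho was -0.800 for this relation, -0.400 for PDX1 and INS and -0.800 for NKX6-1 and CHGA. Each of these rests on 4 cultures. On the TPM scale these 3 were 0.200, 0.800 and 0.200, but the 2 farthest cultures were not the same on both scales. Whether the scale or the cultures left out changed the sign cannot be told apart. In simulated data, 38% to 49% of 2-fold changes were found, so genes not called at this depth and number of samples may have changed by 2-fold.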

Other observations

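The test of other splits was planned, and COL3A1 and DCN in S230 were singled out after their values were seen. Among the metabolic and stress lists, each call in this paragraph was lost with an estimated correlation. At stage 1, 15 of 16 unfolded protein response genes rose (adjusted p = 0.000671, and 0.448 with an estimated correlation), such as HERPUD1, of the degradation of misfolded proteins (4.7-fold), and at stage 2, 14 fell and 1 rose (adjusted p = 0.00132, and 0.478 with an estimated correlation). At stage 2, 16 of 18 hypoxia and glycolysis genes fell (adjusted p = 1.75e-06, and 0.26 with an estimated correlation), with lactate dehydrogenase LDHA down 11.6-fold from 2726 ± 1093 CPM (SD, n = 7) to 235 ± 24.8 CPM (SD, n = 6). The RNA quality list moved the same way, with 7 of 13 mitochondrially encoded genes lower at stage 2 and 12 adjusted over the list alone (adjusted p = 0.0703, and 0.00672 to 0.0443 under the 6 settings where it passed, without S230 among them), and a mitochondrial share of counts of 2.45% ± 1.20 (SD, n = 7) at stage 1 and 1.57% ± 0.672 (SD, n = 6) at stage 2. At stage 4 against stage 3, 11 of the 18 hypoxia and glycolysis genes rose and 1 fell (adjusted p = 1.79e-05, and 0.3 with an estimated correlation), LDHA 5.65-fold. Of 14 cholesterol synthesis genes, 13 fell at stage 2 (adjusted p = 2.03e-09, and 0.091 with an estimated correlation), including the sterol sensor INSIG1 (5.82-fold), and 6 rose at stage 4 (adjusted p = 0.000314, and 0.3 with an estimated correlation). Of 11 immediate early and heat shock genes, 5 rose at stage 4 (adjusted p = 0.00106, and 0.213 with an estimated correlation), with JUN up 5.89-fold. Adjusted over the list alone, 15 unfolded protein response and 17 hypoxia genes fell at stage 2 and 13 hypoxia and 10 cholesterol genes rose at stage 4, and the other counts of this paragraph were the same.

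Of 4 thyroid hormone targets, 3 rose at stage 5 against stage 4, and 4 adjusted over the list alone (adjusted p = 2.53e-08, and 3.25e-05 with an estimated correlation). KLF9, a zinc-finger factor induced by the thyroid hormone receptor, rose 44.4-fold to 53.1 ± 15.8 CPM (SD, n = 6; log2 change 5.47 ± 0.41, adjusted p = 7.04e-13), and the receptor gene THRB rose 6.43-fold to 107 ± 23.7 CPM. Collagen COL3A1, a fibroblast product, was at 745 CPM in the stage 4 library and 748 CPM in the stage 5 library of S230, against 13.6 ± 22.0 CPM (SD, n = 6) and 31.8 ± 47.5 CPM (SD, n = 5) in the other libraries. At stage 0 and stage 3 COL3A1 was also higher in S230, at 3.59 and 15.5 CPM against 0.0722 ± 0.0834 CPM (SD, n = 4) and 0.849 ± 1.55 CPM (SD, n = 6). DCN, a proteoglycan of connective tissue, was at 218 CPM in S230 at stage 5 and 5.38 ± 7.91 CPM in the others.

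Of the 100 splits of the samples of each pair of stages, no other called as many genes as the real one. This share, 1 in 100, is the smallest that 100 splits can show, so a random grouping is made unlikely but not excluded. The splits treat the libraries as independent, which the labels do not state. In a fit of both stages alone, the real split and the highest other split called 9264 and 2969 genes at stage 1 against stage 0, 6093 and 0 at stage 2 against stage 1, 3129 and 2720 at stage 3 against stage 2, 4185 and 959 at stage 4 against stage 3, 3997 and 1 at stage 5 against stage 4, and 11297 and 8035 at stage 5 against stage 0. At stage 5 against stage 4, where the numbers pair the samples, 64 splits parted every shared number, and the highest other of them called 2816 genes, each being a split that exchanged the stages within at least 1 number.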
